A study of Homo sapiens with 70 samples.

How the data were processed

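The data are two-colour cDNA array measurements of 35 human lymphoblastoid cell lines, with 2 arrays per line. Per the labels, each array set the RNA of an individual's line against a pool of control lines. The values were deposited by the authors as 1 log2 ratio per spot in a table of the whole series. The file does not state the log base. Base 2 was inferred from the values, which run from -13.5 to 13.9, and every fold printed rests on it. How the authors made the ratios (image software, background correction, normalization, dyes) is not given in the sources used here. The direction of the ratio is not stated per the labels either, and no 2 of the 2415 pairs of arrays correlated below -0.3 (the lowest r was -0.129). Repeated spots on an array correlated at a median r of only 0.188. A reversed array need not fall below -0.3, so this does not settle whether any array was reversed. The deposited array medians ran from -1.21 to 0.85 log2 units, so the ratios had not been centred per array. Lines were grouped, and their arrays numbered 1 and 2, by the sample titles per the labels. No columns were identical between arrays.

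Spots were named through the platform annotation of GEO, as supplied with the series. The 11520 spots are 5760 clones at 2 places each: for all 3598 annotated clones both places carried the same sequence record. Of the clones, 3300 had 1 gene symbol, 298 several and 2162 none. Of the clones with 1 symbol, 3295 matched the RefSeq gene table by gene number, and 0 symbols changed. No gene was named from a clone with several symbols. The 7 clones of genes that could reveal a donor's sex were left out of every step.

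Each array was centred on its median, and the 2 spots of a clone were averaged on the log2 scale. Clones with values on both arrays of at least 28 of the 35 lines were tested, 4990 in all. Differences between lines were tested with limma 3.58.1 in R 4.3.3 (moderated F-test over the 35 line means, empirical Bayes variances, Benjamini-Hochberg adjustment, threshold 0.05), without covariates. The F ratio printed is the plain ratio of mean squares. The between-line SD is the square root of the variance component, and the span is the fold between the 10 and 90 percentiles of line means. The resemblance of duplicate arrays was tested with 10000 random pairings of the arrays. Differences from the pool were tested with limma on the line means against 0. The 21 gene lists, these main tests and the alternatives said below to be fixed in advance were set before the data were examined. Lists with at least 5 measured members, 1 clone per gene, were set against 10000 random lists of the same size, once by the percentile of the F ratio and once by the correlation of members over lines with each member taken from a different array. A p with an estimated correlation came from 100 bootstrap resamples of the lines.

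The genes named were set by a rule: the 15 genes with the highest moderated F, the 10 called genes with the largest between-line SD, the 2 called members with the highest moderated F of each list with at least 5 measured members, and the 5 genes with the smallest SD of line means among those with a value on all 70 arrays. Clones with several symbols and the genes left out above were excepted, and each gene was taken from its clone with the most values, ties going to the first in the file. The rule gave 52 genes, of which 48 were called. Genes named outside the rule are said to be chosen after their values were seen.

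The scripts were tested on simulated data for 4990 clones in which 200 clones varied between lines. The F-test recovered 2.99%, 41.8% and 100% of these at between-line SDs of 0.5, 1 and 2 times the within-line SD, and called 6 of 4790 unchanged clones. For the comparison with the pool, it recovered 22.5% of 200 clones shifted by 0.5 SD and called 2 unchanged ones. In a simulation of the list tests over 2579 genes, the list made to vary had an adjusted p of 0.0016 in both tests, and 0 of 14 unrelated lists were called. The members of that list shared a line factor with the same SD as the noise, and weaker variation was not simulated.

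Alternatives fixed in advance were the values without centring, scale and quantile normalization between arrays, clones complete on all 70 arrays, clones with both arrays in at least 10 lines, the linear ratio scale, the replicate number as a block, removal of the difference between the 2 ranges of label numbers (16 and 19 lines), each line and each array left out in turn, the mean of all clones of a gene, a plain F-test, moderated F-tests with trend or robust variances, an adjusted p under 0.01, array weights, and at least 1.5-fold from the pool. Alternatives chosen after seeing the data were the removal of local drift (each spot minus the median of its neighbours in a window of 7 by 7 spots), spots crossed or matched between arrays, arrays with under 80% of spots left out, clone values whose spots lay over 2 log2 units apart left out, array covariates, and restrictions of the called clones. The layout of 72 spots per row was inferred from the correlation of neighbouring spots, since the table gives only the spot number. On that layout, removal of drift lowered the correlation of spots next to each other from 0.183 to 0.067. For spots 1 row apart it fell from 0.185 to 0.075. Some drift may therefore remain wherever its removal is named below. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.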

Results

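Gene expression was measured in 35 human lymphoblastoid cell lines, which are B cells made to grow without limit by Epstein-Barr virus (EBV). Each line came from a different person, and each was hybridised on 2 two-colour cDNA arrays against a pool of control lymphoblastoid lines, giving 70 arrays. The series title names the question as natural variation of human gene expression, and the duplicate arrays give the error against which differences between lines can be set. Each array carried 11520 spots, made of 5760 cDNA clones spotted at 2 places. Between 7896 and 10921 spots had a value on an array (68.5% to 94.8%). The arrays were noisy: the repeated spots of a clone on the same array correlated across clones with a median r of 0.188 (range -0.021 to 0.430 over arrays; clones are not independent replicates). For such arrays their number limits the precision. The labels do not say whether the 2 arrays of a line came from separate cultures. The p-values of the F-test therefore set lines only against the spread between arrays, which may be technical. Those of the comparison with the pool use the spread between lines.

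The first comparison asked which genes differed between the cell lines. Variation between lines was widespread: 2203 of 4990 clones tested (44.1%) and 1092 of 2579 genes with a clone of their own (42.3%) differed between lines by the limma moderated F-test at a Benjamini-Hochberg adjusted p under 0.05. The clone of ACTG2, the smooth muscle gamma actin, had the highest F ratio of those tested, though not the widest spread. Its line means spanned 6.11-fold between the 10th and 90th percentile of lines, with a between-line SD of 0.96 log2 units against a within-line SD of 0.23 (70 values, F = 36.3, limma adjusted p = 1.54e-14), and its duplicate arrays correlated at r = 0.945 over the 35 lines. The F ratio of ACTG2 was 10.4 with a different spot of the clone taken from each array of a line and 14.2 with 2 components of variation over arrays as covariates, settings chosen after the data were seen, and it was called in both. Actin genes have very similar coding sequences, so a cDNA clone of this kind can also take up transcript of other actins.

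The 14 other genes with the highest moderated F came from several unrelated functions. PCSK6, a proprotein convertase, had a between-line SD of 0.83 log2 units and a 3.77-fold span between the 10th and 90th percentile of lines (70 values, F = 12.3, limma adjusted p = 9.42e-09). PLN, phospholamban, which restrains the calcium pump of the sarcoplasmic reticulum, spanned 3.41-fold (62 values, limma adjusted p = 1.02e-06), and IFI44L, an interferon-induced gene, spanned 3.81-fold (66 values, limma adjusted p = 6.8e-07). ST3GAL6, a sialyltransferase, spanned 2.83-fold. RPP30, a subunit of ribonuclease P, spanned 2.42-fold, and its other clone on the array was called as well (F = 5.71). PIGM, a mannosyltransferase of glycosylphosphatidylinositol anchor synthesis, spanned 2.13-fold. TRDMT1, a tRNA cytosine methyltransferase, spanned 7.71-fold with a between-line SD of 1.33 log2 units (63 values), and KCNJ15, an inward-rectifier potassium channel, had a between-line SD of 1.08 (68 values). NOC3L, a nucleolar protein, and FMN1, a formin that nucleates actin filaments, had F ratios of 11.5 and 12.4.

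For several of these genes the F ratio depended on 1 line. A line with a value on only 1 array also entered the F ratio, with no duplicate to check it. Over lines with both arrays, duplicates correlated at r = 0.0695 for SUSD6, 0.280 for NOC3L, 0.413 for TIPARP, 0.451 for TRDMT1 and 0.464 for CREB1. For the rest of the 15 genes r ran from 0.533 for IFI44L to 0.945 for ACTG2. TIPARP, an ADP-ribosyltransferase induced through the aryl hydrocarbon receptor, had an F ratio of 21.3 over all lines and 2.89 without 1 line, while its line means spanned 1.95-fold between the 10th and 90th percentile. The F ratio fell from 10.3 to 2.88 for RASGRP3, an activator of Ras in B cells, and from 9.64 to 2.68 for CREB1, a cyclic AMP-responsive transcription factor. That of SUSD6 fell from 9.78 to 1.70, which ended its call (limma adjusted p = 0.133). NOC3L fell from 11.5 to 4.50 and FMN1 from 12.4 to 5.80, both still called. Across all clones, 1432 of the 2203 called clones (65.0%), among them the clones of 674 genes, were called in each of the 35 fits that left out 1 line. For 5 of the 15 genes (RPP30, ST3GAL6, TRDMT1, PCSK6 and KCNJ15) an adjacent clone on the array followed the same pattern over lines, with cross-array correlations of 0.720, 0.675, 0.655, 0.481 and 0.451, above the 0.411 that 95% of clones lying 10 rows apart stayed under. Each value is the highest over up to 4 clones, adjacent or 10 rows away. Of the 14 genes that could also be set against clones 10 rows away, PCSK6 being the exception, 4 exceeded 0.411 with an adjacent clone. With a clone 10 rows away 2 did, a difference that was not significant (exact paired test, two-sided p = 0.688). The clones of further named genes correlated above 0.411 with an adjacent clone as well: those of LYN, INSIG1, YIPF6, HNRNPD, CD3G, IFITM3 and TIMP2. Those of YIPF6 and TIMP2 also did so with a clone 10 rows away (0.528 and 0.655).

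**Figure D1:**
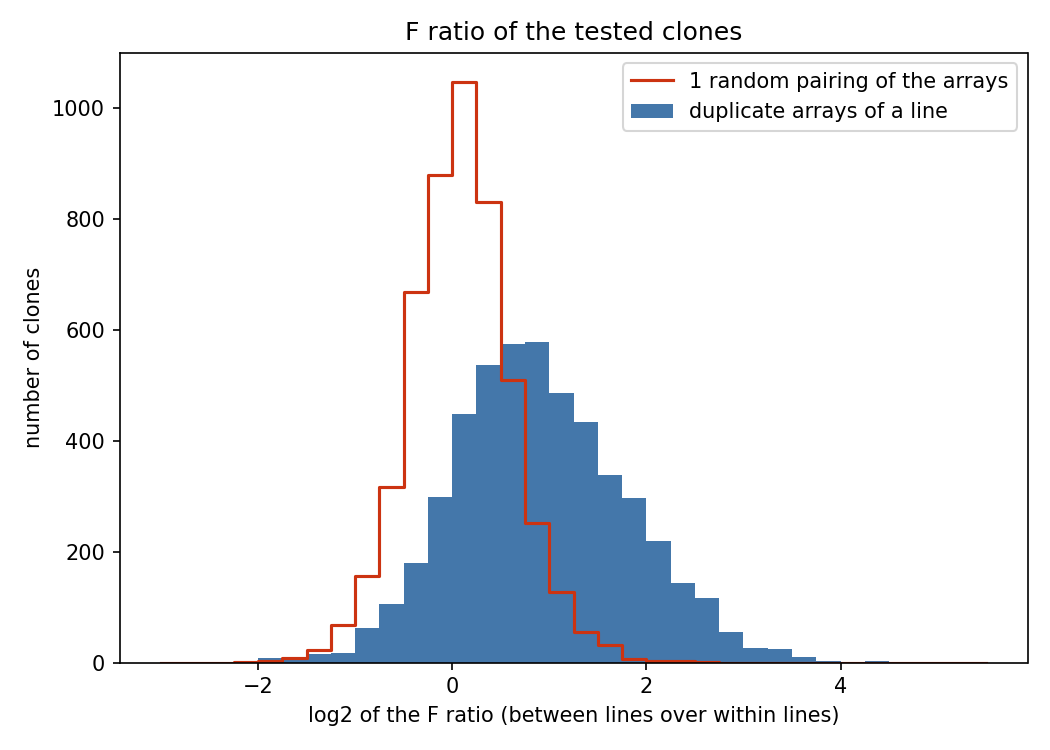
The horizontal axis is the log2 of the F ratio (mean square between lines over mean square within lines) and the vertical axis the number of the 4990 clones tested. Bars show the duplicate arrays of each line, with a median F of 1.81, and the line shows 1 random pairing of the same 70 arrays, which lies around an F ratio of 1.

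**Figure D2:**
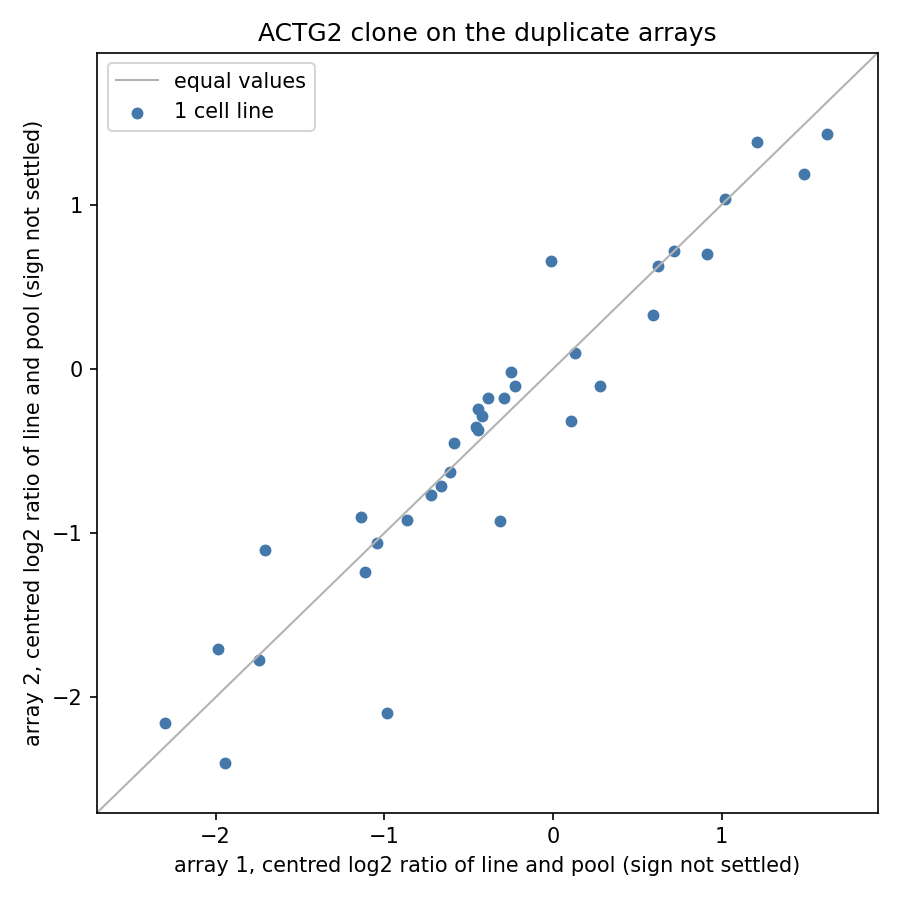
Each of the 35 points is 1 cell line, with the centred log2 ratio of the ACTG2 clone between line and pool on its first array (horizontal axis) and second array (vertical axis); which channel was divided by which is not settled, so the sign has no reading. The grey line marks equal values, and the points lie along it with r = 0.945.

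The genes with the largest spread between lines included surface, nuclear and metabolic proteins. CD44, the hyaluronan receptor, had the largest between-line SD, 1.56 log2 units, and spanned 14.9-fold between the 10th and 90th percentile of lines (66 values, F = 4.84, limma adjusted p = 6.52e-05). PFKFB3, which sets the level of the glycolytic activator fructose 2,6-bisphosphate, had an SD of 1.27 and a span of 4.84-fold (limma adjusted p = 1.24e-05). NUP160, a nuclear pore protein, spanned 8.60-fold, PTPRB, a receptor tyrosine phosphatase, 8.09-fold, YIPF6 7.09-fold, DENND1C 6.07-fold and BLTP2 14.3-fold. These wide spans came with wide error: the within-line SD was 1.09 log2 units for CD44, 1.29 for PTPRB and 1.61 for BLTP2. HNRNPD, an RNA-binding protein, spanned 8.42-fold, but its other clone was not called (F = 1.27, limma adjusted p = 0.262). The call of DNMT1, the maintenance DNA methyltransferase, was lost without 1 line (F from 3.79 to 1.21, limma adjusted p = 0.310). Over lines with both arrays, its duplicates correlated at r = 0.115, against 0.350 to 0.508 for the other genes with the largest SD. Without 1 line the between-line SD fell from 1.27 to 0.82 for PFKFB3, from 1.38 to 0.87 for NUP160 and from 1.26 to 0.79 for DENND1C, all of which were still called. At the other end, the 5 genes with the smallest SD of line means were UVRAG, SCPEP1, PAPOLA, HCCS and TAF7, whose lines spanned 1.33-fold to 1.49-fold. Of these, TAF7 was called (limma adjusted p = 0.0395, and 0.143 without 1 line), and the other 4 were not. Once local drift was removed, however, UVRAG and PAPOLA were called (limma adjusted p = 0.000109 and 0.00532). The between-line SD of UVRAG rose from 0.13 to 0.34 log2 units with that step.

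Over all 4990 clones the median F ratio was 1.81 (quartiles 1.23 and 2.82). The median within-line SD was 0.64 log2 units and the median between-line SD 0.35. The share of variance lying between lines, the repeatability, had a median of 0.293 and exceeded 0.5 for 1155 clones (23.1%). The median between-line SD, from which the error is removed, was 0.45 log2 units for the called clones against 0.35 for all clones. The span of observed line means still holds that error, and its median was 2.22-fold for called and 2.42-fold for uncalled clones. Clones with no gene name here were called about as often, 903 of 1946 (46.4%). When the local drift of the ratio over the array surface was removed, a step chosen after the data were seen, 1863 clones were called, 1691 of them shared with the 2203. With the first spot of a clone taken from 1 array of each line and the second spot from the other, which also was chosen after the data were seen, 1216 of 3372 clones were called. Of the same 3372 clones 1640 were called with both spots averaged, and 990 were called both ways. Of the named genes with such values, SUSD6, CREB1, CANX, IRF4, CDC25B, PSMA3, PSMD12, ATP5PB, PFKL and TAF7 were then not called. With 2 components of variation over arrays as covariates, likewise chosen afterwards, 1054 clones were called, and LYN, FCER2, TNFRSF17, CD70, IFITM3, IL16, CKS1B, PFKL, IDI1, CD3G, TIMP2 and TAF7 were not among them. The components were computed from these same values, and their scores correlated between duplicate arrays (r = 0.772 and 0.827 over lines). As covariates they also take out variation between lines, so a call lost this way need not be an effect of the array.

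The second comparison asked whether arrays of the same line resembled each other more than arrays of different lines. They did, weakly. With each gene centred on its mean, the correlation across clones averaged 0.183 ± 0.097 (SD, n = 35 pairs) for the duplicate arrays of a line and -0.016 ± 0.087 (SD, n = 2380 pairs) for arrays of different lines, a difference of 0.199. The two-sided permutation p was 1e-04, the smallest that 10000 random pairings can give. Of the 70 arrays, 31 had their own duplicate as the array they correlated with best. On the linear ratio scale the difference was 0.0233 (permutation p = 0.368).

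The third comparison asked which kinds of genes varied. Called members were spread over lists of immune, cell cycle and metabolic genes, and no list stood apart from random lists of genes. Of the EBV and NF-kB activation targets, 5 of 9 were called (7 adjusted over the list alone), led by CFLAR, an inhibitor of death receptor signalling (2.68-fold span, limma adjusted p = 3.66e-05), and CD70, a ligand of the tumour necrosis factor family (1.95-fold, limma adjusted p = 4.84e-05). Of the B cell identity genes, 5 of 8 were called (6 adjusted over the list alone), with LYN, a Src-family kinase of B cell receptor signalling, spanning 1.83-fold and FCER2, the low-affinity IgE receptor CD23, 1.88-fold. Once local drift was removed 3 of the 8 were called, and only LYN was called in each of the fits that left out 1 line: the adjusted p (limma) rose to 0.0793 for FCER2, and to 0.137, 0.159 and 0.0604 for CR2, SPIB and MS4A1, which are named after their values were seen. Of the plasma cell genes, 2 of 5 were called (2 adjusted over the list alone): IRF4, a transcription factor of plasma cell differentiation (2.56-fold), and TNFRSF17, the B cell maturation antigen (1.99-fold). The cell cycle list had 8 of 14 members called (9 adjusted over the list alone), among them CDC25B, a phosphatase that activates cyclin-dependent kinases (2.86-fold), whose other clone was not called (F = 0.609), and CKS1B, a cyclin-dependent kinase subunit (2.04-fold).

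Immune signalling genes varied in part. Of the interferon response genes, 5 of 14 were called (5 adjusted over the list alone), 8 of 14 once local drift was removed, and 3 in each of the fits that left out 1 line. They included IFI44L and IFITM3, a membrane protein that restricts virus entry (2.23-fold), whose clone correlated at 0.693 with an adjacent clone. Of the cytokine and receptor genes, 3 of 7 were called (3 adjusted over the list alone), among them IL4R, the interleukin-4 receptor alpha chain (1.79-fold, limma adjusted p = 7.62e-05), and IL16 (1.92-fold). Of the HLA class I and peptide processing genes, CANX, the chaperone calnexin, was the 1 of 5 called (4.08-fold; 1 adjusted over the list alone).

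Among housekeeping and metabolic lists, 4 of 5 actin cytoskeleton and adhesion genes were called (5 adjusted over the list alone), headed by ACTG2 and CD44. In the oxidative phosphorylation list 4 of 11 members were called (7 adjusted over the list alone), with COX6B1 spanning 3.81-fold and ATP5PB 1.83-fold. In the proteasome list 3 of 5 were called (3 adjusted over the list alone), with PSMA3 at 1.83-fold and PSMD12 at 6.10-fold, the latter not called once local drift was removed (limma adjusted p = 0.0854). In the list of cholesterol and fatty acid synthesis 2 of 6 were called (2 adjusted over the list alone): INSIG1, which holds back the sterol-regulated transcription factors (3.22-fold), and IDI1, isopentenyl diphosphate isomerase (3.65-fold, but limma adjusted p = 0.139 once local drift was removed). Of the apoptosis genes 4 of 10 were called (5 adjusted over the list alone), led by CFLAR and BCL2L1, which encodes the survival protein BCL-XL (5.98-fold). Only PFKL, the liver-type phosphofructokinase, was called among 6 glycolysis genes (1 adjusted over the list alone; 2.24-fold, limma adjusted p = 0.00813, and 0.0673 without 1 line). None of 6 genes of xenobiotic and glutathione metabolism was called (0 adjusted over the list alone).

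Markers of other cell types were measured as well. Of the T and NK cell markers 1 of 6 was called (1 adjusted over the list alone), CD3G, whose call was lost without 1 line (limma adjusted p = 0.132) and once local drift was removed (limma adjusted p = 0.371). Of the fibroblast and matrix genes 3 of 6 were called (3 adjusted over the list alone), among them TIMP2, a metalloproteinase inhibitor (2.48-fold), and COL5A1, a collagen chain (1.95-fold). The clone of TIMP2 correlated at 0.705 with an adjacent clone, and at 0.655 with a clone 10 rows away. For 5 lists too few members were measured for a test. The list of HLA class II and antigen loading had 4 genes with 1 called, and that of ribosomal proteins 4 with 1 called. There were 2 monocyte markers with 1 called, 1 heat shock gene with 0 called and 0 immunoglobulin genes. Adjusted over the list alone, the counts were 1, 1, 1, 1 and 0. The called members, named after their values were seen, were CTSS, RPL10 and CD163. Likewise named afterwards, HLA-DQA1 and HLA-DPA1 were not called (limma adjusted p = 0.171 and 0.261).

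In the other lists, the calls that held in each of the fits that left out 1 line numbered 5 of 5 for the EBV and NF-kB targets, 2 of 2 for plasma cell genes, 5 of 8 for the cell cycle, 2 of 3 for cytokines and receptors, 1 of 1 for HLA class I, 3 of 4 for actin and adhesion, 2 of 4 for oxidative phosphorylation and 2 of 3 for the proteasome. They numbered 2 of 2 for cholesterol synthesis, 4 of 4 for apoptosis, 0 of 1 for glycolysis, 0 of 1 for T and NK cell markers and 2 of 3 for fibroblast genes. Once local drift was removed, the count became 3 for plasma cell genes, 7 for the cell cycle and 2 for cytokines and receptors. It became 2 for the proteasome and 3 for actin and adhesion, and did not change for the other 9 lists. In some of these 9 the called members changed. Of the EBV and NF-kB targets EBI3 was lost and BCL2A1 gained, and for cholesterol synthesis IDI1 was lost and FDPS gained. EBI3, BCL2A1 and FDPS are named after their values were seen.

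Of the 16 lists tested, 0 differed from 10000 random lists in the mean percentile of the F ratio after Benjamini-Hochberg adjustment, and 1 had an unadjusted p under 0.05. That was the actin cytoskeleton and adhesion list, with a mean percentile of 77.6 (p = 0.0314, Benjamini-Hochberg adjusted p = 0.410 against random lists; adjusted p = 0.000498 with an estimated correlation). With correlation estimated by resampling the lines, which takes the members as fixed and leaves out the chance of which genes were measured, 4 lists had an adjusted p under 0.05. Besides the actin list these were the EBV and NF-kB targets, at a mean percentile of 65.5 (adjusted p = 0.0201 with an estimated correlation, 0.424 against random lists), and below the middle glycolysis, at 29.4 (adjusted p = 0.0201 with an estimated correlation, 0.410 against random lists), and xenobiotic metabolism, at 27.4 (adjusted p = 0.0182 with an estimated correlation, 0.410 against random lists).

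**Figure D3:**
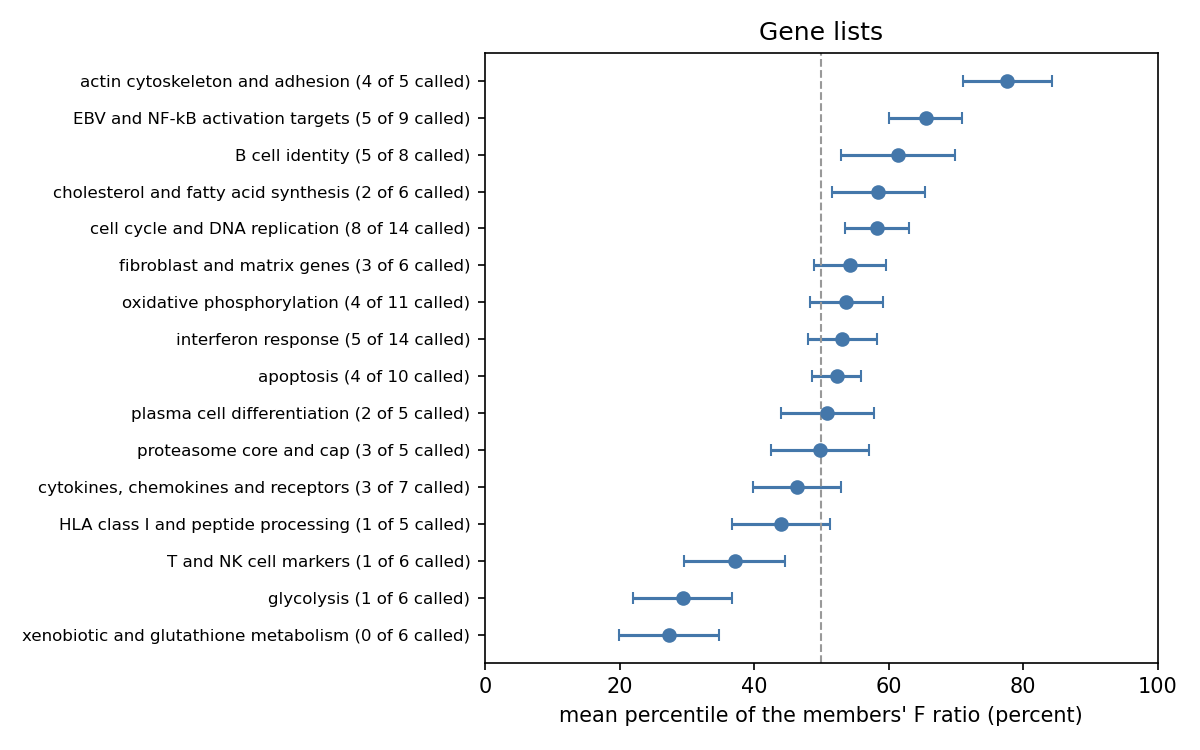
The horizontal axis is the mean percentile of the members' F ratio among the 2579 genes tested, for 16 gene lists, with the called and measured members of each list in parentheses. Error bars are 1 SD over 100 resamplings of the 35 lines, and the dashed line marks 50, the mean for genes taken at random; the lists run from 27.4 to 77.6.

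No list was found whose members varied together over lines more than random genes. The list made to vary in the simulation had 14 members. They shared a line factor with the same SD as the noise, and genes outside that list did not vary. In the data the median SD over all clones was 0.35 log2 units between lines and 0.64 within lines. What the test can find in shorter lists, or where members share less variation, is therefore not known. The mean correlation between members, taken across different arrays, was tested for the same 16 lists against 10000 random lists, and 0 lists passed Benjamini-Hochberg adjustment. The interferon response list came closest, with a mean r of 0.047 between members against 0.00635 over all pairs of genes (p = 0.0492 by permutation of genes over random lists, Benjamini-Hochberg adjusted p = 0.732), and was the 1 list with an unadjusted p under 0.05.

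The last comparison set the mean of the 35 lines against the pool. The 5 largest mean differences among named clones, read off after the values were seen, were those of SAFB2, a nuclear matrix attachment factor, at 1.39 ± 0.26 log2 units (SE, n = 35 lines, limma adjusted p = 0.000464), KIFAP3, a kinesin-associated protein, at 1.19 ± 0.22 (SE, n = 34 lines, limma adjusted p = 0.000408), MAML1, a coactivator of Notch signalling, at 1.16 ± 0.25 (SE, n = 34 lines, limma adjusted p = 0.00158), HNRNPD at 1.12 ± 0.27 (SE, n = 35 lines, limma adjusted p = 0.00382), and NCF4, a subunit of the phagocyte NADPH oxidase, at 1.07 ± 0.21 (SE, n = 34 lines, limma adjusted p = 0.000634). In all, 708 of 4990 clones (14.2%) differed from the pool by limma at a Benjamini-Hochberg adjusted p under 0.05, and 143 of them by at least 1.5-fold. The labels do not settle which channel was divided by which, so only sizes are given: 489 clones had one sign and 219 the other. Of the 708, 283 also varied between lines. Once local drift was removed, 539 clones were called, 373 of them shared with the 708. The pool is a single reference whose own spread is left out, and without centring the arrays 283 clones were called. The dyes are not given either, so a dye effect shared by all arrays cannot be told apart from a difference from the pool.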

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

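The position, spot-crossing, array-selection and covariate settings and the restrictions of called clones were chosen after seeing the data; the others were fixed in advance. The 2203 clones that varied between lines stayed within 1.5 times that count under scale and quantile normalization, the linear scale, looser filtering, other F-tests, array weights, removal of the label-range difference and of local drift (1863), without the arrays with few spots (1639) or discordant spots (2079), and with the array median as a covariate (1869). The count was 3667 without centring, where each array's own offset enters every clone, 1367 at an adjusted p under 0.01, 1221 of the 1907 clones complete on all 70 arrays, 1432 for clones called in each fit that left out 1 line, and 1176 for clones with 1 symbol; the last 4 are smaller by construction. Using only 1 spot per array gave 1216 and 1282 with crossed spots (the first of 3372 clones, of which the averaged spots called 1640, with 990 shared). It gave 1390 with the same spot on both arrays and 1191 with crossed spots after removal of drift. Fewer clones were tested with 1 spot, which does not account for the whole fall, and the cause of the rest was not tested. With 2 array components as covariates the count was 1054, but these components also hold variation shared by the 2 arrays of a line. Leaving out 1 line gave 2022 to 2205 calls and leaving out 1 array 1982 to 2334. With the replicate number as a replicate block 2145 clones were called; same-numbered arrays of different lines did not deviate together (mean r -0.001, range -0.120 to 0.097), so the numbers do not pair arrays, and the block changed no other call. The difference between same-line and different-line correlations kept its sign and passed its permutation test except on the linear scale (0.0233), where the cause was not tested. In the other settings it ran from 0.173 after removal of drift to 0.327 for clones complete on all 70 arrays. It was 0.299 without the arrays with few spots and 0.303 without discordant spots. Without 1 line it was 0.20 to 0.212 and without 1 array 0.199 to 0.212. Against random lists, no list was called under any setting run, in either list test; with correlation estimated by resampling lines, 4 lists passed for the F ratio at the main setting. The 708 clones that differed from the pool became 283 without centring and 143 with at least 1.5-fold (59 after removal of drift as well). Removal of drift alone gave 539, of which 373 were shared with the 708. The count was 267 of the complete clones, 399 without the arrays with few spots and 426 without discordant spots. Fewer clones were tested in these last 3. Leaving out 1 line gave 580 to 777 calls and 1 array 617 to 731. Of the 48 called named genes, 6 lost the call in some fit without 1 line (CD3G, DNMT1, FCER2, PFKL, SUSD6 and TAF7). The call was lost for 12 with the 2 array components as covariates and for 8 on the linear scale. It was lost for 3 each after removal of drift and under quantile normalization, and for 2 under scale normalization. With crossed spots 10 lost it among the genes that could be tested. The 10 genes with the largest between-line SD, CD44 among them, had too few values for that test. The spread between duplicate arrays limits all of these results.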

Other observations

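Of the tests below, those of local drift, of shared labelling, of the array component and of the 15 genes against clones 10 rows away were chosen after the result was seen; the random pairings were planned, but what they would show was written down only afterwards. The component over arrays with the second-largest share of variance (11% of that of 1907 clones measured on all arrays) held genes of several kinds. The genes with the largest weights in it, named after their values were seen, were ACTG2, HNRNPU, a nuclear RNA-binding protein, CAPZA2, an actin-capping protein, TCF7L2, a transcription factor of Wnt signalling, NAP1L1, a histone chaperone, RBM39, EIF4A1, a helicase of translation initiation, and SFPQ, a splicing factor, all on the same side, against SEPTIN6 on the other side. The scores of duplicate arrays correlated at r = 0.827 over the 35 lines.

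That component may follow the dye balance of the array rather than the cells. Over the 35 lines its scores correlated with the deposited median ratio of the arrays (r = 0.653, permutation p = 4e-05; rho = 0.702, permutation p = 2e-05; r = 0.699 without the 2 most extreme lines; Benjamini-Hochberg adjusted p = 0.00012 and 6e-05 over 3 relations), whereas the first component, with 12.6% of the variance, gave r = 0.115 (permutation p = 0.51; rho = 0.234, permutation p = 0.18; r = 0.0737 without the 2 lines; adjusted p = 0.51 and 0.18). ACTG2 itself correlated with the array median at r = -0.413 (permutation p = 0.013; rho = -0.403, permutation p = 0.017; r = -0.460 without the 2 lines; adjusted p = 0.0195 and 0.0255). Its variation was not explained by the array median alone, since its F ratio stayed at 31.7 with the median as a covariate (limma adjusted p = 4.32e-13), and it was 14.2 with both components as covariates. The second component gives ACTG2 its largest weight, so that covariate takes out part of the gene's own variation. Whether the component holds differences between the cells as well stays open, as no biological group is given by the labels.

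Of 100 pairings of the 70 arrays, only the real pairing, 1 of 100, gave as many as 2203 clones, and the highest of the 99 others gave 66, so chance can be excluded. After removal of the drift of the ratio over the array surface, 1863 clones were called, where the highest random pairing gave 83. Adjacent spots still correlated after that step (r = 0.067, against 0.183 before). The part of the drift that was taken out is therefore not the whole cause, and the drift that stayed was not tested. Signal shared with a neighbouring spot may add to the calls: 31.1% of called clones followed an adjacent clone, and 8.68% a clone 10 rows away, above the level that 95% of all clones 10 rows apart stay under. Of the 15 genes with the highest moderated F, 5 followed an adjacent clone, but over the 14 that had both values the counts were 4 and 2, too few to decide, since the bound of 3 set beforehand took no account of how repeatable these genes are; 427 genes were called with and without removal of drift, in each fit without 1 line and without such a neighbour. Labelling, culture or day shared by the arrays of a line cannot be told apart from the line itself, because the medians of duplicate arrays correlated (r = 0.854, permutation p = 1e-05, the smallest the resampling can give; rho = 0.786) and the labels name no separate cultures.

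Calls that were lost without 1 line were set against the noise of the lines. They include calls near the threshold that do not rest on 1 line. For MS4A1 the F ratio went only from 2.19 to 1.92 (limma adjusted p from 0.0287 to 0.0604). Of the 2203 called clones, 771 lost the call when 1 line was left out. The line farthest from the others, which need not be the line whose removal ended the call, was the same in at most 8.82% of them. No line was therefore the farthest in most of these clones, which does not show whether some line was aberrant. The number of such clones per line rose with the within-line SD of the line (rho = 0.554, permutation p = 0.00076, and r = 0.634, permutation p = 0.00011). Without the 2 most extreme lines r was 0.660. Clones were assigned to the line with the farthest mean, and a noisier line is the farthest more often whatever the cause of a call. The relation therefore cannot decide whether noisier arrays of some lines were a source of these calls. Expression differences of single lines stay open, as no biological explanation was tested.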
